A study of Caenorhabditis elegans with 18 samples.

How the data were processed

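Small RNAs and messenger RNAs were measured in whole Caenorhabditis elegans grown at 20 C, in 18 libraries that the labels put into 9 groups of 2. The mixed-population groups on NA22 were sRNA libraries of N2 and of 4 independently made meg-3 meg-4 lines. Per the labels these carry the same meg-3 allele, ax3055, with the meg-4 alleles ax3052, ax4310, ax4311 and ax4312 in lines 1 to 4. The young-mother groups on HT115 with the L4440 vector were mRNA libraries of N2 and line 1 and sRNA libraries of N2 and of rde-11(hj37). Per the labels' protocols RNA for sRNA libraries was treated with 5' polyphosphatase and built with a TruSeq small RNA kit, and RNA for mRNA libraries was depleted of ribosomal RNA and given ERCC control RNAs. Per the submitters' processing notes cutadapt, Bowtie2, HISAT2, HTSeq and DESeq2 were used with genome build ce10, without versions or roles. The annotation, the strand setting and the filters are not stated in the sources used here, so sRNAs are described as mapping to a gene and sense and antisense reads were not told apart. Of 157 named genes 155 could be placed in a later build, and 50 of them overlap another protein-coding gene on some strand, which makes the assignment of their sRNAs uncertain. Coordinates are not printed for this reason.

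The sRNA tables hold RPM per library, as deposited by the authors, with columns that sum to the same total. The mRNA table holds a scaled signal per library, as deposited by the authors, whose columns differ slightly in their sums. Per the file headers each table also holds a log2 fold change and p-values with an adjusted form, made by the authors before deposit, and those were used for a count of calls and, at some genes, for an adjusted p set beside the ones made here. Whole reads were recovered from the deposited values by dividing each column by the value of 1 read, estimated from its low values, and 100% of values were then whole within 0.02. The 4 mixed tables contain the same 2 N2 libraries and 42400 genes each, and 42048 genes were listed in each of the others. The 352 genes found only in the mixed tables took 1.28 to 2.53% of reads. Gene names were matched to biotypes for 98.5% of the mixed and 99.3% of the other entries. ERCC control RNAs are not among the genes of the mRNA table, so scaling by them was not done.

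Depth was 4.21 and 3.82 M (1e6) reads in the N2 mixed libraries, 4.07 and 4.10 in line 1, 6.52 and 5.41 in line 2, 6.57 and 5.26 in line 3 and 7.47 and 5.87 in line 4. The mRNA libraries of young mothers held 45.2 and 44.3 M in N2 and 21.99 and 44.9 in line 1, and the sRNA libraries 4.26 and 4.85 M in N2 and 4.06 and 4.93 in rde-11. The planned test for counts was edgeR, and because the tables hold normalized values the stated fallback was used in its place. This was limma 3.58.1 with a mean trend in R 4.3.3 on log2(value + 1), for genes with a mean of at least 10 over the 4 libraries of a table. Calls needed a Benjamini-Hochberg adjusted p below 0.05. The added 1 makes fold changes of genes near 10 RPM smaller than their ratios, and a fold limit for a gene without reads takes 3 reads per group as its floor. Each comparison was tested within its own table.

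On simulated data the fit recovered 61.1, 63.8, 58.1 and 62.4% of 2-fold changes in the settings of lines 1 to 4 (7012, 6945, 7036 and 6991 genes). It recovered 100% in the mRNA setting (7514 genes) and 95.7% in the rde-11 setting (7757 genes). For 4-fold changes it recovered 100, 100, 97.8, 98.9, 100 and 100%. False calls made up 12.4, 11.0, 4.08, 7.36, 5.37 and 3.26% of calls, above the nominal level in lines 1, 2 and 4 and in the mRNA setting.

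Gene lists were tested with limma camera at a fixed correlation of 0.01 where at least 5 members were tested. Results were adjusted over the lists of a comparison, and the test was repeated with an estimated correlation. That estimate rests on the few libraries of a table, which leaves the repeat little power. A list that it did not call is therefore left undecided by it. The 24 lists were double-stranded RNA uptake and RNAi, mutator genes, nuclear RNAi, Argonautes, 26G and ERI genes, piRNA biogenesis, P granule components, histones, ERGO-1 class targets, nuclear RNAi target examples, microRNA genes, the mir-35 family, piRNA genes and oocyte and eggshell genes. Further lists were early zygotic genes, major sperm proteins, other sperm genes, yolk proteins, collagens, intestine, muscle, neurons, heat shock and the intracellular pathogen response. Overlaps were tested with Fisher's exact test. The comparisons, the lists, the tests and the rule for naming genes were set before the data were examined.

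Named genes were meg-3, meg-4, rde-11 and sid-1 in every comparison and up to 12 called members of the first 7 lists. They also were the 8 higher and 8 lower genes with the largest log2 change (at least 10 in both libraries of the higher group and no overlap of replicates), and up to 4 called members of each further called list. Added to these were the 10 higher and 10 lower genes with the largest smallest change over the 4 lines. In line 1 they included the 8 genes with more sRNA and less mRNA and the 8 with the reverse, by adjusted p of the mRNA. Genes named outside this rule are said to have been looked up afterwards.

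Alternatives were scaling by relative log expression (RLE), by library size or by summed microRNA reads, no filter and pseudocounts of 0.5 and 10. Further alternatives were DESeq2 1.42.0 on recovered reads, a replicate block, a single fit of the 10 mixed libraries and leaving out each library. TMM scaling with the same limma fit and edgeR 4.0.16 on recovered reads were added after the data were seen. Replicate numbers were not used as pairs because the labels name no shared animals or day. The deviations of equally numbered replicates correlated at 0.515, 0.0781, -0.125, -0.214, 0.229 and 0.404 in lines 1 to 4, mRNA and rde-11, with only 2 pairs each. Genes below the filter, and tests of lists with fewer than 5 members, were left out.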

Results

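Small RNAs (sRNAs) and messenger RNAs of Caenorhabditis elegans lacking the germ granule proteins MEG-3 and MEG-4 were compared with those of the wild-type strain N2. sRNAs of rde-11 mutants were compared with N2 in a separate experiment. All values below are group means ± SD with n = 2 libraries per group, in RPM for sRNAs and in scaled signal for mRNAs. The log2 values are mutant against N2 with the standard error (SE) or adjusted p from limma. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples. The sRNA libraries of the 4 meg-3 meg-4 lines came from mixed populations on NA22 bacteria, whereas the mRNA libraries of line 1 and the rde-11 sRNA libraries came from young mothers on HT115 bacteria with the L4440 vector. The group characteristic of line 2 reads young mother while its title and source read mixed population, and the title was followed.

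Replicates correlated at 0.958 in N2 mixed libraries and at up to 0.995 elsewhere, and their chi-square per degree of freedom ran from 3.18 to 23.4, so no pair was as close as repeated sampling of the same reads. MicroRNA genes took 22.2 and 27.1% of reads in the N2 mixed libraries, 29.3 and 32.2% in line 1, 32.5 and 35.5% in line 2, 33.8 and 31.1% in line 3 and 34.0 and 38.3% in line 4. A larger share for some genes lowers the RPM of all others. The median log2 over all tested genes was -0.336, -0.562, -0.590 and -0.771 in lines 1 to 4, against -0.036, -0.109, -0.0473 and -0.181 after scaling by trimmed mean of M-values (TMM). Changes of gene groups are therefore given relative to the median of all genes. Counts over all genes are given under both scalings, and those of some lists only for the values as deposited. In young mothers the medians were -0.110 for mRNA and 0.163 for rde-11 sRNAs, with TMM values of -0.0843 and 0.0488.

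The mutated genes were lost from the mRNA of line 1: meg-3 fell from 93.4 ± 1.51 to 0.298 ± 0.0199 (log2 -6.19, SE 0.098, adjusted p = 9.09e-08). No read of meg-4 was found in line 1 against 44.4 ± 1.15 in N2, a loss of at least 1010-fold. Among sRNAs meg-4 went from 42.2 ± 9.96 in N2 to 0 in lines 1 and 2, at least 115-fold and 168-fold lower, and to 0.323 ± 0.189 and 0.304 ± 0.0514 in lines 3 and 4. sRNAs mapping to meg-3 averaged 16.03 ± 4.52 in N2 and 0.369, 1.15, 0.609 and 0.627 in lines 1 to 4, below the filter of the limma test. edgeR, which tested them, gave log2 -5.02, -3.12, -4.09 and -3.93 (adjusted p = 0.00949, 0.0523, 0.00153 and 0.00302). In rde-11 mutants sRNAs mapping to rde-11 itself were 640 in N2 and 742 in the mutant (log2 0.21, adjusted p = 0.107), which does not test the mutation, as the labels do not describe the allele. There meg-3 sRNAs were 12.4 and 17 (0.42, adjusted p = 0.115), while meg-4 sRNAs rose from 71.2 to 139 (0.95, adjusted p = 0.00095).

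sRNAs mapping to rde-11, a gene needed for RNA interference (RNAi) by supplied double-stranded RNA, rose in all 4 meg-3 meg-4 lines. From 389 ± 42.1 in N2 they reached 3767 ± 275 in line 1 (log2 3.28, adjusted p = 1.05e-13) and 1616 ± 66.3 in line 2 (2.06, 1.1e-16). Lines 3 and 4 reached 920 ± 146 (1.24, adjusted p = 3.51e-06) and 1911 ± 3.99 (2.30, 6.62e-15). Its neighbour B0564.2 rose from 50.3 ± 1.72 to 2905 ± 20 (5.82), 549 ± 166 (3.39), 374 ± 148 (2.81) and 751 ± 77.5 (3.87). Its values in lines 2 and 3 were looked up after those of lines 1 and 4 had been seen. sRNAs mapping to sid-1, which encodes a channel for double-stranded RNA, went from 460 ± 28.4 to 661 ± 64.9 in line 1 (0.52, adjusted p = 0.0816) and 745 ± 24.2 in line 2 (0.70, 0.00245). In line 3 they rose to 2821 ± 61 (2.61, adjusted p = 8.14e-16) and in line 4 to 705 ± 2.56 (0.62, 0.013). The sid-1 gain of line 1 passed under TMM (0.83, adjusted p = 0.00692). Without replicate 1 or 2 of the line the changes in lines 2 and 4 stayed as large but were no longer called. They were 0.66 and 0.73 in line 2 (adjusted p = 0.182 and 0.156) and 0.62 and 0.61 in line 4 (0.157 and 0.17). The Argonaute pseudogene wago-2, followed after its mRNA had been seen, went from 411 to 591, 595, 597 and 576 (adjusted p = 0.0813, 0.0182, 0.0224 and 0.0462), and hrde-1 sRNAs were not called in any line. Levels of 6 genes in each mixed library are drawn below.

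**Figure D1:**
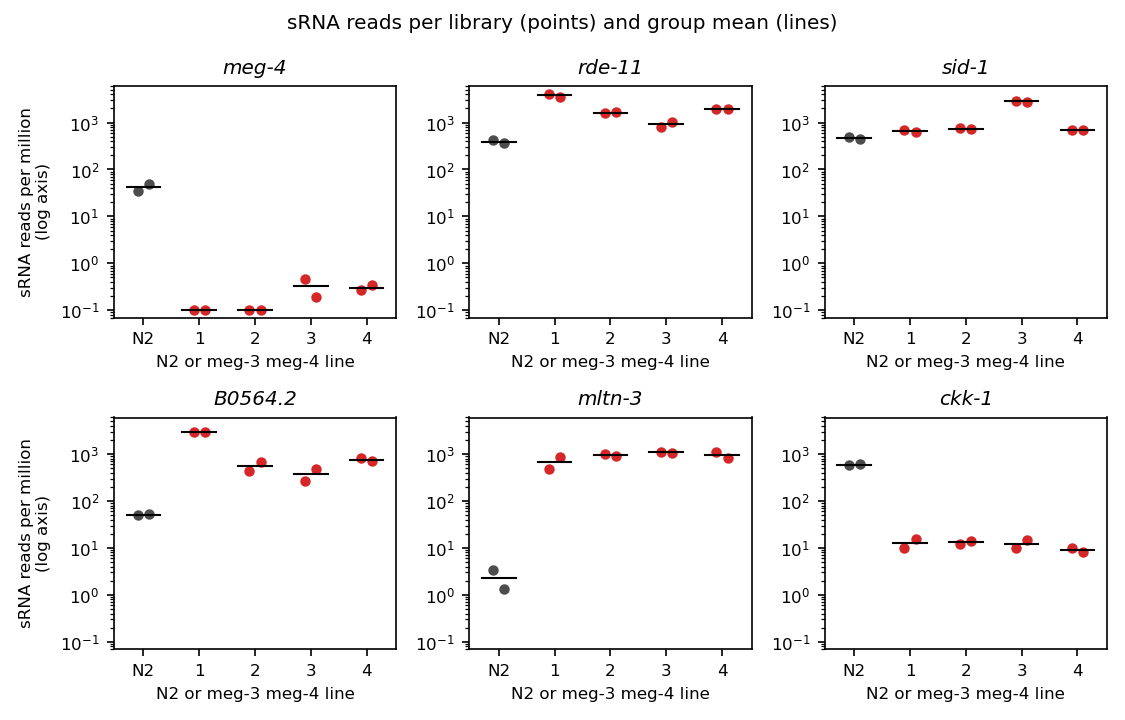
sRNAs (RPM) mapping to meg-4, rde-11, sid-1, B0564.2, mltn-3 and ckk-1 in each mixed-population library of N2 and meg-3 meg-4 lines 1 to 4. Points are libraries, lines are group means of n = 2, the axis is logarithmic and values under 0.1 are drawn at 0.1.

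In all 4 lines 151 genes gained and 823 lost sRNAs of 6480 tested in each, and 151 and 367 of these passed under TMM as well, which alone called 358 and 367. Lists independent of each other would share 0.0331 higher and 186 lower genes (1.09 and 0.618 under TMM), although the lines were all compared with the same N2 libraries and so are not independent. In 50 simulated sets without any difference at most 1 gene was called higher and 0 lower in all 4 lines. The simulation gave every library the same spread per gene and no shift in composition. It may therefore understate errors from the shared N2 pair, whose chi-square per degree of freedom was 17.7 against 7.14 to 12 in the lines. The 151 genes included 120 protein-coding genes, 10 genes for small nucleolar RNAs and 8 microRNA genes. Without N2 replicate 1 the counts were 184 and 717, and without N2 replicate 2 they were 236 and 1756.

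The largest shared gain was at mltn-3, from 2.32 ± 1.42 to 684 ± 280, 951 ± 70.5, 1088 ± 36.3 and 968 ± 177 in lines 1 to 4 (log2 7.70, 8.23, 8.43 and 8.25). sRNAs mapping to F41C3.8, which overlaps F10G7.10, rose from 12.3 to 562, 781, 671 and 514 (5.40, 5.88, 5.66 and 5.27). The thiamine pyrophosphokinase gene tpk-1 rose from 109 to 2264, 1442, 1975 and 1799 (4.40, 3.75, 4.20 and 4.07), and B0261.8 from 59.9 to 1261, 599, 987 and 715 (4.37, 3.30, 4.02 and 3.55). The soluble guanylyl cyclase gene gcy-35 rose from 4.66 to 64.3, 76.0, 80.7 and 74.9 (3.58, 3.82, 3.90 and 3.78). C07G1.7 rose from 2.88 to 24.0, 33.8, 40.6 and 47.0 (3.25, 3.65, 3.98 and 4.19), and pals-27 by 3.64, 3.34, 3.76 and 3.63. The gains were 3.24, 3.41, 3.96 and 3.84 for hrg-9, 3.17, 3.23, 3.40 and 3.80 for rpr-1, the RNA of ribonuclease P, and 3.20, 3.14, 3.22 and 3.20 for T16H12.2. Each of these 10 genes was called in every line under TMM too. C07G1.7 was at 0 and 5.76 in the N2 libraries, and edgeR did not call it in line 1 (adjusted p = 0.0856) nor did the deposited values in any line (adjusted p = 0.777, 0.458, 0.352 and 0.284).

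Besides meg-4, shared losses were led by ckk-1, which encodes a kinase of calmodulin-dependent kinases and fell from 595 ± 24.1 to 12.9, 13.2, 12.4 and 8.89 (log2 -5.46, -5.40, -5.50 and -5.92). sRNAs mapping to the ciliary gene bbs-5 fell from 347 ± 11.5 to 12, 5.75, 5.84 and 8.23 (-4.77, -5.72, -5.68 and -5.24). The cyclin-dependent kinase gene cdk-14 fell from 213 to 6.38, 8.21, 4.55 and 7.90 (-4.89, -4.57, -5.28 and -4.84), and prx-11 from 332 to 16.42, 8.56, 8.56 and 8.86 (-4.25, -5.12, -5.11 and -5.07). The synaptic gene rimb-1 changed by -4.61, -4.21, -4.48 and -4.42, kal-1 by -4.50, -4.44, -4.30 and -4.63, and the ceramidase gene asah-1 by -4.29, -4.41, -4.20 and -4.40. The chemoreceptor gene srt-47 changed by -4.45, -4.52, -4.85 and -4.89 and T25D3.3 by -4.33, -4.40, -4.41 and -4.30. Against this citk-1, next to mltn-3 by its sequence name, fell only from 232 ± 17.6 to 89.6, 99.3, 90.3 and 65.5 (-1.36, -1.21, -1.35 and -1.81).

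Line 1 called 207 genes higher and 939 lower of 6821 tested in RPM, and 433 and 526 under TMM, so the share of gains was 18.1% or 45.2%. Besides the shared genes named above, and not always in this line alone, the F-box gene fbxa-125 rose from 14.7 ± 4.01 to 310 ± 228 (log2 4.10, adjusted p = 1.02e-10) and Y53H1B.2 by 4.15. sRNAs of ndx-2, which also fell in line 2, went from 460 to 15.3 (-4.86). Y54G2A.42, also lower in lines 3 and 4, changed by -5.63 and Y20F4.9 by -4.67. Cuticle collagen genes lost sRNAs: col-111 from 353 to 23.4 (-3.93), col-38 from 57.0 to 8.45 (-2.63), col-103 by -2.66 and col-162 by -1.96. Of 9 collagen genes 6 were lower, or 8 adjusted over the list alone, with a median of -0.667 relative to all genes (adjusted p = 0.000235, but adjusted p = 0.995 with an estimated correlation). Of the RNAi machinery eri-9 (-0.80, adjusted p = 0.0263), henn-1 (-0.71, 0.0445) and mut-2 (-0.79, 0.0349) fell in RPM. None of these 3 passed under TMM. Without single libraries their changes ran from -1.06 to -0.52 and were not called without N2 replicate 1 (adjusted p = 0.234, 0.18 and 0.105), line 1 replicate 1 (0.141, 0.369 and 0.0592) or replicate 2 (0.361, 0.215 and 0.627). Without line 1 replicate 1 or 2 the counts of all genes were 124 and 546, or 103 and 468, and without N2 replicate 2 they were 461 and 1905.

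In line 2, 389 genes were higher and 3526 lower of 6678 (9.94% higher), against 814 and 663 under TMM (55.1%). The aldolase gene aldo-1 rose from 19.2 to 250 ± 136 (log2 3.57) and F57G4.7 by 3.45, and ndx-2 changed by -5.05. The helicase gene emb-4 (-1.07), nrde-4 (-1.12) of nuclear RNAi and nyn-1 (-1.11) fell in RPM, as did the Argonaute gene csr-1, from 407 to 199 (-1.03), and the germ granule helicase gene glh-1, from 300 to 156 (-0.94). The median of all genes was -0.562 in this line. Under TMM 1 P granule gene was called lower, meg-4, so glh-1 was not. The nyn-1 call was lost without line 2 replicate 1 (adjusted p = 0.068), and those of csr-1 and glh-1 without line 2 replicate 1 (0.059 and 0.0606) or replicate 2 (0.0522 and 0.116), with changes of -0.86 to -1.05. Without line 2 replicate 1 or 2 the counts were 150 and 839, or 162 and 739.

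In line 3, 388 genes were higher and 3616 lower of 6653 (9.69% higher), against 1068 and 577 under TMM (64.9%). sRNAs mapping to pqn-24 rose from 0.606 to 156 (log2 6.63), ZK177.9 by 4.65 and frpr-13 by 3.98, while the mechanosensory channel gene trp-4 fell from 405 to 13.5 (-4.82) and Y54G2A.42 changed by -5.23. The Argonaute gene rde-1 changed by -1.28 in RPM, whereas ego-1 (-1.02), glh-1 (-1.11) and csr-1 (-1.01) fell but were not called without line 3 replicate 1 (-0.96, -1.07 and -0.96). The median of all genes was -0.59 in this line. Under TMM 0 of 15 mutator genes were called lower, ego-1 being a member of that list. Without line 3 replicate 1 or 2 the counts were 150 and 629, or 173 and 1294.

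In line 4, 356 genes were higher and 4394 lower of 6590 (7.49% higher), against 896 and 861 under TMM (51%). ZK177.9 gained by 4.24, the axon regeneration kinase gene dlk-1 fell from 457 to 15.96 (log2 -4.76) and Y54G2A.42 changed by -4.80. Of the machinery eri-9 (-1.25, TMM -0.66 with adjusted p = 0.0307), henn-1 (-1.26, TMM -0.67 with 0.0196) and nrde-4 (-1.21, TMM -0.62 with 0.0317) fell under both scalings. So did mut-2 (-1.18, TMM -0.60 with adjusted p = 0.0382), glh-1 (-1.16, TMM -0.55 with 0.0364) and emb-4 (-1.15, TMM -0.55 with 0.0365). Of these 6 edgeR called only henn-1 (adjusted p = 0.0489), the others being at log2 -0.57 for eri-9, -0.52 for nrde-4, -0.49 for mut-2, -0.42 for glh-1 and -0.44 for emb-4 (adjusted p = 0.0682, 0.0678, 0.107, 0.104 and 0.0812). The deposited values called none of the 6 (adjusted p of 0.0877 to 0.406). The sRNAs of prg-2, rsd-6, snpc-4 and pid-3 (-1.08, -1.05, -1.11 and -1.10) were called in RPM alone. Without line 4 replicate 1 or 2 the counts were 193 and 2540, or 179 and 1817.

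MicroRNA genes gained as a group in all 4 lines at the fixed correlation, but in none with an estimated correlation. In line 1, 14 of 105 were higher and 2 lower (14 and 2 adjusted over the list alone). The counts were 49 and 6 of 106 in line 2 (48 and 6 over the list alone), 40 and 11 of 103 in line 3 (36 and 9) and 55 and 6 of 106 in line 4 (54 and 6). Their medians relative to all genes were 0.724, 0.963, 0.962 and 1.31 (adjusted p = 3.35e-20, 3e-23, 1.04e-21 and 7.62e-35; adjusted p = 0.995, 0.788, 0.645 and 0.919 with an estimated correlation). Under TMM 39, 63, 73 and 78 were higher and 1, 2, 2 and 2 lower, and by edgeR 8, 53, 49 and 76 were higher and 1, 2, 1 and 1 lower. mir-54 rose by log2 1.66, 1.49 and 1.52 and mir-249 by 1.88, 1.87 and 2.13 in lines 2 to 4, while mir-257 fell from 48.0 to 7.34, 12.06, 5.63 and 8.93 (-2.59, -1.88, -2.99 and -2.27). Of 7 mir-35 family genes, active in oocytes and embryos, 0 were called in line 1 by limma or edgeR (list adjusted p = 0.985). In contrast 5, 5 and 6 were higher in lines 2 to 4 (6, 5 and 6 adjusted over the list alone). The family's medians were 1.35, 1.38 and 1.52 above all genes (adjusted p = 4.04e-07, 2.24e-07 and 1.45e-07; adjusted p = 0.788, 0.645 and 0.919 with an estimated correlation). Calls of mir-35, mir-37 and mir-40 were lost, at changes of 0.35 to 0.65, without N2 replicate 2 in line 2 (adjusted p = 0.105, 0.0819 and 0.0802) and line 4 (0.181, 0.176 and 0.151), and without line 3 replicate 1 in line 3 (0.0552, 0.172 and 0.235). In line 2 those of mir-37 and mir-40 were also lost without line 2 replicate 1 (log2 0.68 and 0.60, adjusted p = 0.078 and 0.137).

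Genes for piRNAs lay above all genes by 0.256, 0.32, 0.408 and 0.52 in lines 1 to 4 (adjusted p = 0.000352, 0.000435, 2.4e-05 and 1.29e-07; adjusted p = 0.995, 0.788, 0.345 and 0.943 with an estimated correlation). Even so single piRNA genes were mostly called lower in RPM. The counts were 0 higher and 3 lower of 383, 11 and 75 of 370, 15 and 69 of 370 and 13 and 90 of 370 (0 and 1, 5 and 47, 7 and 44, and 5 and 60 adjusted over the list alone). Under TMM they turned to 3 and 1, 57 and 3, 95 and 4 and 88 and 3. The piRNA gene 21ur-15630 fell under both scalings (log2 -2.32, -2.15, -2.62 and -2.68), as did 21ur-4880 in lines 2 to 4 (-1.93, -1.86 and -2.04), though not by edgeR in line 4 (-1.40, adjusted p = 0.0535). Targets of ERGO-1 class siRNAs were not called as a list in line 1 (adjusted p = 0.525). They lay above all genes in lines 2 to 4, by 0.69, 0.876 and 0.789 (adjusted p = 0.00774, 0.000818 and 0.0489, but adjusted p = 0.788, 0.645 and 0.919 with an estimated correlation). Their own median log2 in RPM was 0.128, 0.286 and 0.0184 in lines 2 to 4, and their mean in line 4 was -0.0648. There 3 and 1, 3 and 0, and 2 and 1 of 9 were higher and lower, with the same counts adjusted over the list alone. Under TMM the counts were 5 and 0, 6 and 0, and 5 and 1. F39F10.4 changed by -1.51 in line 4 while F55C9.3 rose by 0.97, 0.75 and 0.65. Without replicate 1 of line 2, 3 or 4 F55C9.3 was at 0.82, 0.45 and 0.65 and no longer called (adjusted p = 0.0843, 0.353 and 0.112). In line 4 the same held without N2 replicate 2 (0.45, adjusted p = 0.0516) or line 4 replicate 2 (0.65, 0.118).

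The lists of RNAi machinery were not called in any line of meg-3 meg-4 sRNAs. Counts higher and lower in lines 1 to 4 were 1 and 0, 2 and 7, 2 and 7, and 2 and 9 of 12 genes for double-stranded RNA uptake and RNAi. They were 0 and 1, 0 and 8, 1 and 9, and 0 and 12 of 15 mutator genes. Nuclear RNAi genes had 0 and 0 by limma and edgeR, 0 and 10, 0 and 9, and 0 and 13 of 16. P granule genes, with the mutated meg-4 as a tested member, had 0 higher in each line and 1, 12, 12 and 14 lower of 15 (adjusted p = 0.417, 0.066, 0.0713 and 0.168). The 1 lower in line 1 was meg-4 itself. Oocyte genes had 0 higher and 3, 15, 15 and 16 lower of 18 (adjusted p = 0.525, 0.0613, 0.0671 and 0.163), but under TMM only 0, 2, 2 and 3 were lower. Argonaute genes had 0 and 0 (1 and 0 by edgeR), 1 and 10, 1 and 8, and 1 and 9. The 26G and ERI genes had 0 and 2, 0 and 7, 0 and 7, and 0 and 8. piRNA biogenesis genes had 0 and 1, 0 and 10, 0 and 11, and 0 and 12. In the 7 lists of RNAi and germ granule machinery 0 to 2 members per list were lower under TMM. Collagen genes were not called in lines 2 to 4 (adjusted p = 0.0613, 0.188 and 0.155), nor were histone genes in lines 1 to 4 (adjusted p = 0.417, 0.369, 0.188 and 0.216). The intracellular pathogen response had 1 and 2, 2 and 3, 2 and 3, and 1 and 4 of 8 (adjusted p = 0.985, 0.6, 0.342 and 0.705). Of 4 nuclear RNAi target examples in line 1, 0 were higher and 2 lower, too few for a list test.

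**Figure D2:**
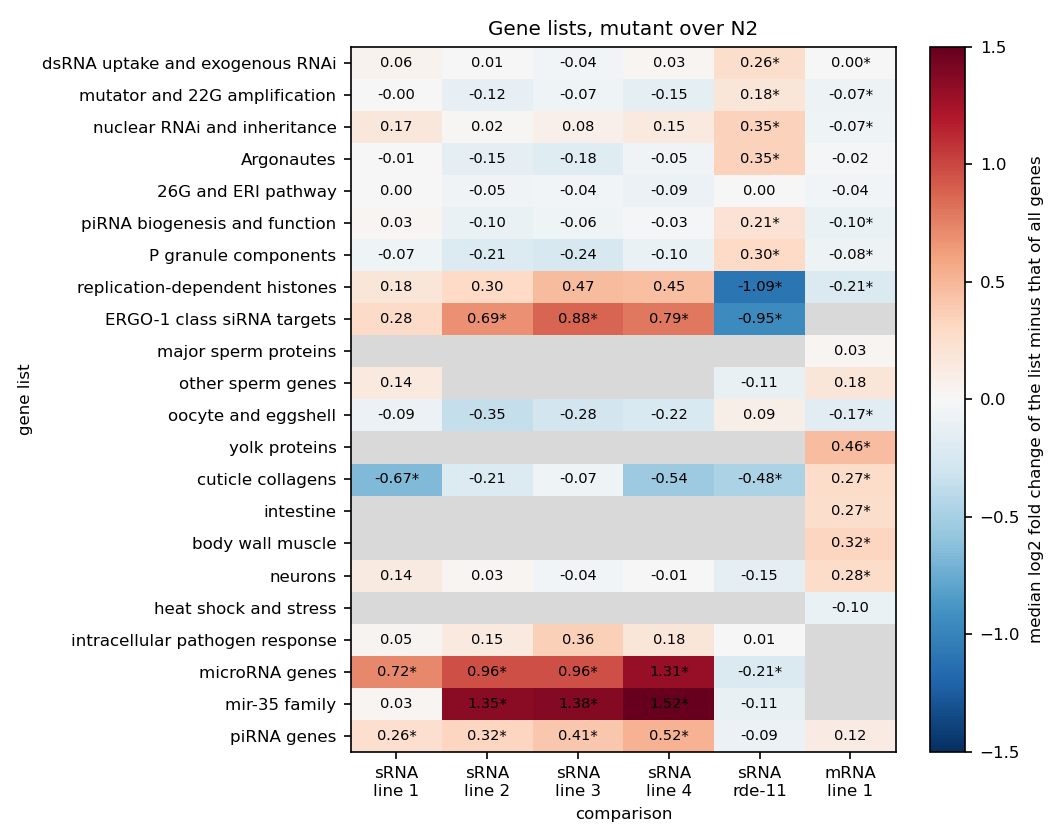
Median log2 of each gene list minus that of all genes (colour) in the 6 comparisons. An asterisk marks lists with adjusted p < 0.05 at the fixed correlation and grey marks lists with under 5 tested genes.

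In the mRNA of line 1 rde-11 fell from 30.5 ± 0.503 to 8.96 ± 0.959 (log2 -1.66, SE 0.099, adjusted p = 0.000125). The Argonaute pseudogene wago-2 fell from 147 ± 1.11 to 58.4 ± 6.12 (-1.32, adjusted p = 0.000125) and sid-1 from 63.0 ± 0.788 to 41.8 ± 2.52 (-0.58, 0.00612). B0564.2 fell from 22.02 ± 2.2 to 4.36 ± 0.746 (-2.11, adjusted p = 0.000131), and the F-box gene fbxa-192 from 44.8 to 9.51 (-2.12, 1.66e-05). Smaller losses were found at eri-6, from 20.3 to 12.02 (-0.71, adjusted p = 0.00709), and eri-7, from 61.2 to 39.3 (-0.62, 0.00612), whose products form a helicase of the 26G pathway. Others were at rde-4 (-0.41, adjusted p = 0.0117), deps-1 (-0.35, 0.0177), mip-2 (-0.34, 0.0258) and the nuclear Argonaute gene hrde-1, from 966 to 752 (-0.36, 0.0278). Gains were led by the scramblase gene scrm-4, from 2.10 to 31.03 (3.37, adjusted p = 6.76e-06), and citk-1, from 39.3 ± 0.243 to 176 ± 1.59 (2.13, 1.97e-06). The p38 kinase genes rose as well, pmk-2, from 5.42 to 25.4 (2.04, adjusted p = 5.9e-05), and pmk-3, from 12.5 to 39.2 (1.58, 8.71e-05). T10D4.6 rose from 20.4 to 78.3 (1.89, adjusted p = 9.16e-06), the fatty acid amide hydrolase gene faah-1 from 39.7 to 118 (1.55, 2.5e-05) and the spermatogenic Argonaute gene alg-3 from 14.8 to 22.1 (0.55, 0.0265). pmk-1, the remaining p38 gene, was looked up afterwards and rose from 15.4 to 40.2 (1.33).

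Of 7616 genes tested 318 mRNAs were higher and 785 lower (28.8% higher), against 294 and 426 under TMM (40.8%) and 332 and 220 by library size alone (60.1%), so the excess of losses depended on scaling. These counts rested on both N2 libraries: without N2 replicate 1 they were 17 and 7, and without N2 replicate 2 they were 24 and 11. The named genes meg-3, meg-4, fbxa-192, scrm-4, citk-1, pmk-2, pmk-3, faah-1, T10D4.6 and B0511.11 stayed called in both cases. The calls of rde-11 (adjusted p = 0.0672 and 0.0577), B0564.2 (0.0672 and 0.0708), wago-2 (0.0672 and 0.0575), sid-1 (0.0757 and 0.124) and hrde-1 (0.0757 and 0.14) were lost without N2 replicate 1 and 2. So were all other calls named by the rule, at adjusted p of up to 0.188, except those of cpr-4 and fbxc-44 without replicate 1. The log2 changes of the 5 genes without N2 replicate 1 and 2 were -1.68 and -1.65 for rde-11, -2.21 and -2.01 for B0564.2, -1.31 and -1.32 for wago-2, -0.59 and -0.57 for sid-1 and -0.37 and -0.35 for hrde-1. These lay close to the values from all libraries, so with 1 N2 library left the calls were lost and not the changes. hrde-1, egl-3 and unc-13 also lost their calls without line 1 replicate 1 (adjusted p = 0.0529, 0.0762 and 0.0638), and unc-13 without replicate 2 as well (log2 0.27, adjusted p = 0.118), so its call rested on all 4 libraries.

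Replication-dependent histone mRNAs were lower by 0.214 than all genes at the median (adjusted p = 5.24e-06, and 0.537 with an estimated correlation). Of 44 genes 21 were lower (14 under TMM and 12 by edgeR), or 28 adjusted over the list alone. his-45 and his-55, which share all their reads, fell from 47.9 to 15.3 (log2 -1.59), his-10 changed by -0.70 and his-63 by -0.48. Oocyte and eggshell mRNAs were lower by 0.165 (adjusted p = 0.000166, and 0.537 with an estimated correlation). Of 21 genes 14 were lower (11 under TMM and 4 by edgeR), or 18 over the list alone. Among them were the maternal genes puf-5, from 586 to 443 (-0.40), spn-4 (-0.37), mex-6 (-0.35) and pos-1 (-0.34). The 3 early zygotic genes were looked up afterwards: vet-1, vet-2 and vet-6 were lower by -0.61, -0.59 and -0.65, and none was called without N2 replicate 1 (limma, adjusted p = 0.0757 for each) or 2 (adjusted p = 0.151, 0.14 and 0.14). piRNA biogenesis genes had 6 of 20 lower (4 under TMM and 1 by edgeR), or 12 over the list alone (median -0.0981, adjusted p = 0.00308). P granule genes, with meg-3 and meg-4 as members, had 6 of 18 lower (5 under TMM and 4 by edgeR), or 11 over the list alone (-0.0807, 0.00318). The mutated meg-3 and meg-4 were among these 6, and the mean of the P granule list relative to all genes was -0.723. Part of its test thus follows from the genotype. Neither list was called with an estimated correlation (adjusted p = 0.537 for both). Genes for double-stranded RNA uptake and RNAi had 4 of 14 lower, and 4 over the list alone, with a test downwards (adjusted p = 0.0407; adjusted p = 0.537 with an estimated correlation) and a mean of -0.202 but a median of 0.00304 relative to all genes. Mutator genes had 2 of 14 lower, or 3 over the list alone (0.0342), and nuclear RNAi genes 1 of 16, or 7 over the list alone (0.0298). With an estimated correlation these were at adjusted p = 0.586 and adjusted p = 0.537.

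The lists of body tissues were higher in line 1 mRNA at the fixed correlation and were not called with an estimated correlation. Yolk protein genes lay 0.461 above all genes with 0 of 6 called by limma or edgeR, or 5 over the list alone (adjusted p = 0.000429; adjusted p = 0.537 with an estimated correlation). Muscle genes lay 0.319 above with 0 of 12 called by limma or edgeR, or over the list alone, and 1 under TMM (adjusted p = 5.24e-06; adjusted p = 0.537 with an estimated correlation). Collagen genes lay 0.273 above with 2 of 37 higher, and 2 over the list alone (adjusted p = 3.04e-06; adjusted p = 0.537 with an estimated correlation), col-95 and col-101 rising by log2 0.54 and 0.45. Intestinal genes lay 0.267 above with 2 of 11 higher, or 4 over the list alone (adjusted p = 0.00104; adjusted p = 0.537 with an estimated correlation), cpr-4 and lys-1 rising by 0.72 and 0.45. Neuronal genes lay 0.276 above with 2 of 10 higher, and 2 over the list alone (adjusted p = 0.00169; adjusted p = 0.537 with an estimated correlation), egl-3 and unc-13 rising by 0.33 and 0.29. The lists of 26G and ERI genes (2 higher and 3 lower of 14, adjusted p = 0.108) and Argonautes (2 and 2 of 19, 0.703) were not called. Nor were major sperm protein genes (0 and 0 of 21 by limma and edgeR, adjusted p = 0.688), other sperm genes (1 and 0 of 12, 0.0778) or heat shock genes (0 and 0 of 7 by both, 0.789). For heat shock genes the median (-0.103) and mean (-0.368) relative to all genes were negative while the test pointed upwards. Without N2 replicate 1 no collagen, histone, oocyte, neuronal, yolk or muscle gene was called. Their medians stayed at -0.212 for histones, -0.149 for oocyte, 0.435 for yolk, 0.32 for collagen, 0.327 for intestinal, 0.339 for muscle and 0.303 for neuronal genes.

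Of the 151 genes with more sRNAs in all 4 lines, 72 were tested for mRNA in line 1: 25 were lower and 5 higher, with a median of log2 -0.236 against -0.110 in other genes. The planned test of this set did not pass (limma camera p = 0.278, and 0.293 with an estimated correlation). A comparison chosen after that result gave 34.7% lower against 13.4% of 4414 other genes (odds ratio 3.43, Fisher's exact p = 4.74e-06) and 6.94% higher against 1.81% (4.04, exact p = 0.0112). Of the genes with fewer sRNAs in all 4 lines 337 were tested, 34 higher and 28 lower with a median of -0.0264 against -0.113. The limma camera test passed upwards (p = 0.00282, and 0.0469 with an estimated correlation). The 111 of them lost under both scalings had 19 higher and 6 lower with a median of 0.132 (limma camera p = 3.29e-13, and 0.0454 with an estimated correlation). All of these counts rest on mRNA calls that fall to 7 to 24 without either N2 library, and sRNAs and mRNAs came from animals of different stage and food.

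Within line 1, 4720 genes were tested for both kinds of RNA. Among the genes with more sRNAs and a called mRNA, 28 fell and 10 rose. This made 73.7% lower against 87.3% of other called mRNAs (614 and 89; odds ratio 0.407, Fisher's exact p = 0.025). This share counts called mRNAs alone, and both lower and higher mRNA calls enter it. Under TMM the shares were 71.4 and 78.7% (exact p = 0.23), and without N2 replicate 1 or 2 the share was 25 or 0%. Genes that gained sRNAs and lost mRNA included, after rde-11 and B0564.2, fbxc-44 (log2 1.37 and -0.998), bath-15 (1.68 and -0.60), F23A7.8 (1.34 and -0.53), bath-2 (0.78 and -0.50), set-23 (1.23 and -0.56) and linc-6 (1.91 and -0.86). The mRNA loss of fbxc-44 was called without N2 replicate 1 but not without replicate 2 (-0.91, adjusted p = 0.0575). The sRNA changes of bath-2 and F23A7.8 were 0.52 and 1.07 without line 1 replicate 1 and no longer called (adjusted p = 0.436 and 0.0539), nor was that of bath-2 without replicate 2 (1.04, adjusted p = 0.0584). Among genes with fewer sRNAs 35 mRNAs rose and 30 fell, 46.2% lower against 90.5% of others (odds ratio 0.0902, Fisher's exact p = 1.07e-16; TMM 20 against 82%, exact p = 3.54e-12). They included scrm-4 (-2.33 and 3.37), citk-1 (-1.36 and 2.13), pmk-3 (-1.76 and 1.58), F28F8.7 (-1.64 and 1.40), Y20F4.4 (-1.45 and 1.01) and tns-1 (-1.82 and 0.58). C18D4.6 (-0.95 and 1.24) was another, but its sRNA loss was no longer called without line 1 replicate 1 or 2 (log2 -1 and -0.89, adjusted p = 0.107 and 0.238). Of these mRNA gains those of scrm-4, citk-1 and pmk-3 stayed called without either N2 library. The pmk-3 loss of sRNAs was not called in lines 2 to 4. Across all genes the 2 kinds of change correlated at -0.0635.

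**Figure D3:**
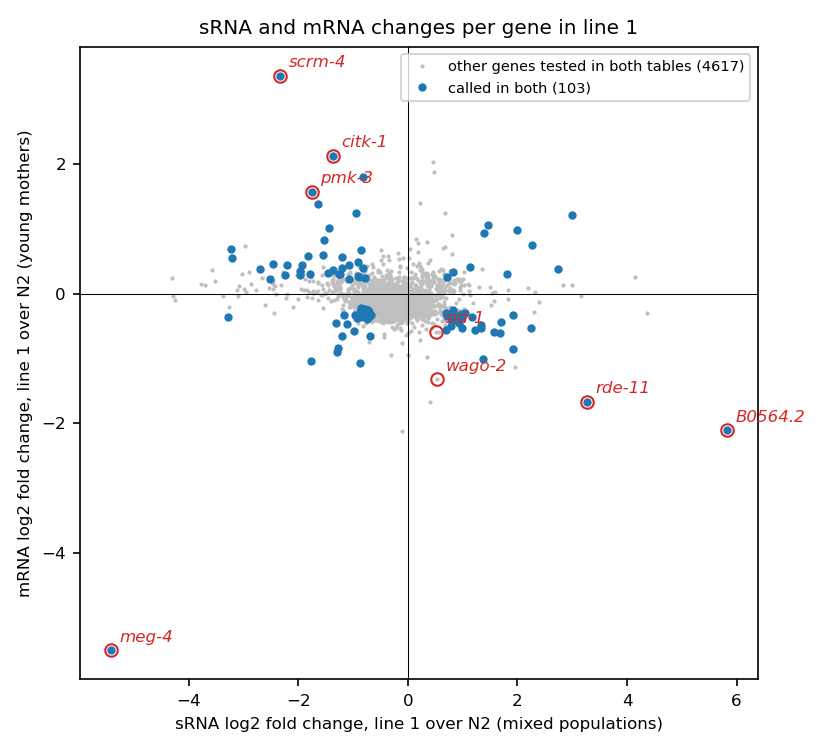
log2 change of sRNAs (mixed populations) against that of mRNA (young mothers) in meg-3 meg-4 line 1. Blue points are the 103 genes called in both, grey points all other genes, and red circles mark meg-4, rde-11, B0564.2, wago-2, sid-1, scrm-4, citk-1 and pmk-3.

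In rde-11 mutants sRNAs mapping to the intestinal transcription factor gene elt-7 rose from 2.51 to 163 (log2 5.55), C18G1.9 from 1.53 to 98.1 (5.29) and T28D6.4 from 22.8 to 288 (3.58). R13H4.5 (3.29), the CREB coactivator gene crtc-1 (3.23), R102.4 (2.86), gem-1 (2.12) and C07G3.8 (2.06) rose as well. The F-box gene fbxa-61 fell from 282 to 1.12 (-7.06), Y110A2AL.1 from 873 to 7.48 (-6.76), bbs-5 from 332 to 8.95 (-5.06) and eri-12 from 190 to 4.98. They were followed by Y47H9C.9 (-4.47), Y37E3.26 (-4.39), clec-166 (-4.15) and the ciliary gene arl-13 (-4.04). Of 7855 genes 1435 were higher and 672 lower (68.1% higher), against 779 and 853 under TMM (47.7%). Without N2 replicate 1 the counts were 232 and 3.5e2, and without rde-11 replicate 2 they were 427 and 463. sid-1 sRNAs were not called (656 and 744, adjusted p = 0.158).

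Histone genes lost sRNAs in rde-11 mutants: 10 of 14 were lower, or 11 with 1 higher over the list alone. Their median was -1.09 relative to all genes (adjusted p = 1.29e-08; adjusted p = 0.329 with an estimated correlation). his-61 fell from 84.7 to 6.92 (log2 -3.45), his-4 changed by -1.53 and his-41 by -1.51. ERGO-1 class targets lost 5 of 8, or 6 over the list alone (-0.952, adjusted p = 9.13e-08; adjusted p = 0.329 with an estimated correlation). E01G4.5 fell from 437 to 93.3 (-2.21), K02E2.6 from 1780 to 903 (-0.98), H09G03.1 by -0.92 and Y37E11B.2 by -0.74. MicroRNA genes had 2 higher and 10 lower of 114, or 2 and 8 over the list alone (-0.212, adjusted p = 0.000107; adjusted p = 0.564 with an estimated correlation), mir-262 falling from 525 to 99.8 (-2.39) while mir-253 rose by 1.33. Collagen genes had 3 of 10 lower, and 3 over the list alone (-0.48, adjusted p = 0.0041; adjusted p = 0.564 with an estimated correlation), with col-111 at -0.64, and at -0.56 and not called without N2 replicate 1 (adjusted p = 0.0668).

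Machinery lists gained sRNAs in rde-11 mutants at the fixed correlation, and with an estimated correlation none was called (adjusted p = 0.564 for each of the 6). Higher were nuclear RNAi genes 10 of 16, or 11 over the list alone (median 0.346, adjusted p = 0.0041), P granule 8 of 16, or 10 (0.3, 0.0041), Argonautes 7 of 14, or 8 (0.349, 0.0267). So were genes of double-stranded RNA uptake and RNAi 7 of 13, and 7 over the list alone (0.26, adjusted p = 0.0267), mutator 6 of 15, or 7 (0.181, 0.0267), and piRNA biogenesis 9 of 19, and 9 (0.214, 0.0399). Under TMM 5, 5, 6, 5, 4 and 5 of these were higher. heri-1 rose from 57.1 to 107 (log2 0.90, adjusted p = 0.00252), glh-2 from 29.0 to 68.3 (1.20, 0.00369) and drh-1 by 0.98. The gains of wago-1 (0.96), snpc-4 (0.92) and ego-1 (0.74) were smaller and no longer called without N2 replicate 1 (log2 0.74, 0.82 and 0.55, adjusted p = 0.093, 0.055 and 0.0956). The 26G and ERI genes (3 of 12 higher, adjusted p = 0.245) and oocyte genes (6 of 18 higher, 0.245) were not called as lists. Nor were the mir-35 family (0 of 7 by limma or edgeR, adjusted p = 0.844) and piRNA genes (17 higher and 13 lower of 952, 0.228).

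Losses were shared between rde-11 mutants and meg-3 meg-4 lines: of 6222 genes tested in all 5 comparisons 222 lost sRNAs in rde-11 and in all 4 lines against 73.6 by independence (odds ratio 5.52, Fisher's exact p = 1.19e-62). They made up 37.4% of the rde-11 losses and 28.8% of the shared meg-3 meg-4 losses, and bbs-5 was among them. Under TMM the numbers were 151 and 41.5 (6.86, exact p = 2.52e-53). The exact test takes genes as independent. The planned limma camera test of the 772 shared losses in rde-11 passed downwards (p = 4.91e-11), but not with an estimated correlation (p = 0.0523). Their median in rde-11 was log2 -0.0886 against 0.183 in other genes. For the 347 losses under both scalings the limma camera p was 2.55e-16, and 0.0843 with an estimated correlation. Gains in the lines met losses in rde-11 at 21 genes against 11.9 (exact p = 0.0085; TMM 86 and 38.5, exact p = 8.43e-14). An example is B0261.8, which fell from 65.5 to 24.3 in rde-11 (log2 -1.40, adjusted p = 0.00243). Losses in the lines met gains in rde-11 at 106 genes against 162 (exact p = 4.95e-08) but at 41 against 38.6 under TMM (exact p = 0.66), as for citk-1, from 373 to 695 (0.90, adjusted p = 0.000378). Shared gains were fewer than by independence, 14 against 26.2 (exact p = 0.00531; TMM 22 and 35.8, exact p = 0.0106). The N2 libraries of the 2 experiments were separate, and stage and food differed between them.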

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

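The tests of scaling and of single libraries below, and that of a microRNA share, of oocyte RNA and of sRNA gains at oocyte genes, were chosen after the results had been seen. Those of a few abundant genes and of the shallower library were written before.

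In a test between lines that was not planned, sRNAs mapping to sid-1 differed between the 4 meg-3 meg-4 lines, with a range of 2.09 in log2 change (limma F test, adjusted p = 7.51e-07). Those of rde-11 differed by 2.04 (adjusted p = 8.76e-06; TMM 1.80, adjusted p = 3.89e-05), highest in line 1 and lowest in line 3. Those of B0261.8 differed by 1.07 (adjusted p = 0.00138; TMM 0.866, adjusted p = 0.00711). Of 130 genes with a range of at least 1 and a test passed under both scalings these 3 were picked, as genes of RNAi or of the largest shared changes, and B0564.2, looked up afterwards, differed by more (3.01, adjusted p = 8.76e-06). sid-1 and rde-11 did not rank the lines alike, since line 3 had the largest gain at sid-1 and the smallest at rde-11.

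The sid-1 gain of line 3 could come from scaling or from 1 library out of place. After TMM scaling the range was 2.34 (adjusted p = 3.64e-06), and 2 of the 2 libraries of line 3 lay above the highest library of the other lines, so neither explanation held. The lines differ in their meg-4 allele and in their separate origin, and with 1 line per allele these were not told apart.

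More genes were called lower than higher in every line in RPM. A larger share of microRNA reads might produce this, but outside microRNA genes the medians were still -0.226, -0.392, -0.45 and -0.556. A few abundant genes may explain more, since the 100 most abundant genes took 43.1 to 43.2% of N2 reads and 50.6, 53.4, 53.1 and 55.9% in lines 1 to 4. Outside these 100 genes the medians were -0.147, -0.301, -0.337 and -0.437 in lines 1 to 4 against -0.336, -0.562, -0.590 and -0.771 over all genes, so the shift was smaller in each line but stayed. Scaled by summed microRNA reads, the medians were lower, at -0.649, -1.01, -0.976 and -1.3. Total sRNA per animal was not measured, so a gain of microRNAs and a loss of other sRNAs were not told apart. No biological explanation was tested.

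The lists of oocyte mRNAs were lower and those of body-tissue mRNAs higher in line 1 at the fixed correlation, but not with an estimated correlation (adjusted p = 0.537 for each), and without N2 replicate 1 no oocyte, yolk, collagen, muscle or neuronal gene was called. A smaller share of oocyte and embryo RNA in the mothers would raise the medians of the 5 body-tissue lists, the lowest of which lay 0.267 above all genes. These lists are part of the pattern to be explained, so their medians do not test that explanation. As to loss through sRNAs gained at oocyte genes, 0 members of the oocyte list had more sRNAs in line 1 under TMM scaling. This count cannot exclude such loss, because the sRNAs came from mixed populations on other food. The fit also recovered only 61.1% of simulated 2-fold sRNA changes in the setting of line 1. The shallower library of line 1 could have caused the shift, but without it the oocyte median was -0.188 relative to all genes. Brood size and staging were not measured in these data.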

How the results depend on the processing

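Of 299 called values of named genes 170 were called under every setting, 196 under every setting that kept all libraries, and 0 turned direction. Library size alone equals RPM for sRNAs, and ERCC scaling was not run. Leaving out a library leaves 1 in a group, which is assumed to vary like the others. The causes of the moves below were not tested. Depth limits sRNA values of genes below 10 RPM, which were not tested.

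Counts are given for lines 1 to 4 in order. TMM gave 433, 814, 1068 and 896 higher and 526, 663, 577 and 861 lower; RLE 419, 860, 1007 and 921 higher and 533, 623, 614 and 662 lower. MicroRNA scaling gave 86, 126, 132 and 98 higher and 925, 4511, 4235 and 5066 lower. DESeq2 gave 364, 699, 775 and 802 higher and 459, 485, 441 and 481 lower, and edgeR 973, 1186 and 1097 higher in lines 2 to 4 and 454, 535, 556 and 545 lower in lines 1 to 4. Without a filter line 1 had 47 higher and 189 lower and line 2 2314 lower. In line 1 the replicate block gave 479 and 2490 and a single fit of 10 libraries 313 and 1615. Leaving out each library gave 103 to 461 and 468 to 1905 in line 1 and 150 to 487 and 739 to 4249 in line 2. It gave 150 to 539 and 629 to 4329 in line 3 and 179 to 398 and 1817 to 4620 in line 4.

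For mRNA no filter gave 71 higher and 43 lower, the replicate block 770 and 1727, and leaving out each library 17 to 472 and 7 to 626. Lower mRNA calls were 426 under TMM, 220 by library size and 229 with edgeR. For rde-11 higher calls were 779 (TMM), 844 (RLE), 2889 (replicate block), 504 (DESeq2) and 904 (edgeR), with 232 to 1394 on leaving out libraries. Lower calls were 1047 (replicate block) and 1290 (edgeR), with 3.5e2 to 574.

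In all 4 lines higher calls were 358 (TMM), 352 (RLE), 54 (microRNA), 43 (no filter), 307 (DESeq2) and 281 (edgeR), and 184 to 236 without an N2 library. Lower calls were 367 (TMM), 370 (RLE), 183 (no filter), 1613 (replicate block), 331 (DESeq2), 316 (edgeR) and 1354 (single fit), and 717 to 1756 without an N2 library.

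The median mRNA change of genes with more sRNAs in all lines (-0.236, p of 0.278 by limma camera) passed without a filter (-0.0147, p of 0.0349) and with the replicate block (p of 0.0359). It also passed with DESeq2 (-0.227, p of 0.0411), edgeR (-0.023, p of 0.035) and TMM sRNA sets (-0.194, limma camera p of 0.0223, but 0.28 with an estimated correlation). Without each library it was -0.236 to -0.204, and passed without line 1 replicate 1 (-0.226, p of 0.0234). The set with fewer sRNAs (-0.0264, p of 0.00282) lost its call without a filter (0.0273, p of 0.274) and with edgeR (0.0924, p of 0.0964), and ran from -0.0409 to -0.0172 without each library. Its direction is that of the camera test relative to all genes, a choice made after the medians had been seen. The raw median also turned positive by library size (0.0282), DESeq2 (0.0116) and TMM sRNA sets (0.132).

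The share of lower mRNAs among line 1 genes with more sRNAs (73.7%, Fisher's exact p = 0.025) was no longer different from other genes under TMM (71.4, exact p = 0.23), RLE (79.4, 0.0894), a pseudocount of 10 (75.7, 0.0758), DESeq2 (73.8, 0.656) and library size (60.7, 0.84). It turned above that of other genes without a filter (62.5, exact p = 0.26), with edgeR (59.2, 0.0481) and without N2 replicate 1 (25, exact p = 1). Without each library it ran from 0 to 70.3, with p = 0.53, 0.56 and 0.0271 by the exact test without N2 replicate 2 and line 1 replicates 1 and 2. The overlap of losses in rde-11 and all lines stayed above independence under the settings run: 151 (TMM), 146 (RLE and edgeR), 175 (microRNA), 80 (no filter), 302 (replicate block) and 108 (DESeq2). It also did so without each young-mother library. No mixed-population library was left out for this overlap, so its dependence on the shared N2 pair is not known.

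Of 37 called gene lists 0 stayed called with an estimated correlation, a test with little power at 4 libraries, which does not decide on them. With the replicate block 34 stayed called. The lists lost there were mutator (adjusted p = 0.0692) and nuclear RNAi (0.0631) in mRNA and ERGO-1 targets in line 4 (0.114).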

Other observations

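The comparison between lines of the mir-35 family, the count of neighbouring gains, the repeats of both neighbour counts without overlapping genes and the test of rde-11 and wago-2 against oocyte mRNAs were chosen after the results had been seen. Only the count of neighbouring losses was written before.

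Lines 2 to 4 differed from line 1 in the mir-35 family, whose microRNAs are made in oocytes and embryos. mir-35 was higher in them than in line 1 by log2 1.21 (limma, adjusted p = 0.00371) and mir-41 by 1.20 (adjusted p = 0.000906). Of the family 6 of 7 members were called, or 7 under TMM, mir-39 being the exception (0.57, adjusted p = 0.0584). The limma F test between all 4 lines did not pass for mir-36, mir-38 and mir-39 (adjusted p = 0.168, 0.0757 and 0.209). The family summed to 26340 ± 11300 RPM in N2, 20040 ± 4620 in line 1, 39810 ± 6340, 41490 ± 12200 and 38660 ± 729 in lines 2 to 4, and 9665 and 9855 in young-mother N2 and rde-11. The N2 libraries held 34330 and 18360, which makes the comparison with N2 uncertain. The comparison between lines has limits too. The share of oocytes and embryos in each mixed population was not measured, so stage and line were not told apart. The group characteristic of line 2 also reads young mother, as given above. Line 1 was sequenced less deeply (4.07 and 4.10 M reads) than lines 2 to 4 (5.26 to 7.47). The members also moved together (estimated correlation of 0.965 to 0.985 in lines 2 to 4), so they are not separate evidence. Of 6356 genes 549 differed between the 4 lines, 288 under TMM and 194 under both, of which 130 had a range of at least 1. Lines 2 to 4 together differed from line 1 at 395 genes under both scalings.

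The authors' deposited adjusted p-values called 367, 702, 775 and 803 genes higher and 462, 485, 441 and 482 lower in lines 1 to 4, 384 and 831 in mRNA and 508 and 567 in rde-11.

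Lower mRNA of rde-11 and wago-2 might reflect a smaller share of oocyte and embryo RNA rather than a change of these genes. The oocyte gene with the largest loss, cav-1, changed by -0.459, against -1.66 (SE 0.099) for rde-11 and -1.32 (SE 0.079) for wago-2, so both fell more than any gene of the oocyte list. Only that list was compared, the histone mRNA his-55 fell by -1.59, and the explanation stays open. These p-values passed only with both N2 libraries, as given above.

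Gains of sRNAs could spread to neighbouring genes. The neighbours rde-11 and B0564.2 both gained sRNAs, but spread between them was not tested. B0564.2 also overlaps best-1 and best-2, which makes the assignment of its sRNAs uncertain. The 120 protein-coding genes with gains in all 4 lines held 4 adjacent pairs among 5673 genes, against a mean of 1.31 and a highest value of 8 in 10000 random sets (permutation p = 0.042). Without overlapping genes 3 pairs stood against 1.16 (permutation p = 0.11), so the test could not tell. The pairs were rde-11 with B0564.2, T23G11.11 with T23G11.1, Y94H6A.12 with Y94H6A.7, and the overlapping F10G7.10 with F41C3.8.

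Losses could likewise fall on neighbouring genes. The 339 genes lost under both scalings held 15 pairs against a mean of 10.5 and a highest value of 26 (permutation p = 0.11). This met the bound set before against the explanation, but that bound was wrong, since a missed threshold with 15 pairs above the mean of 10.5 does not exclude an excess. The test could not tell. Without overlapping genes 15 stood against 9.26 (permutation p = 0.044). The pairs included fbxa-170 with meg-4.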
